A study of Mus musculus with 6 samples.

How the data were processed

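RNA was sequenced from 6 libraries of islet cells from 7-day-old mice, 3 from control and 3 from transformed Ppy-lineage cells. Groups were taken from the sample titles, because the genotype field of the labels gives a different Rosa number to each replicate of a group. Per the labels' protocols, islets were isolated and dispersed and libraries were made with the SMART-Seq HT kit, a poly(A)-primed full-length method for small inputs that does not mark strand. The labels name no sort and no gate by which Ppy-lineage cells were collected. The submitters' processing notes name fastp 0.21.0, STAR 2.5.3a, RSEM 1.3.3 and edgeR 3.32.1 and the mouse build GRCm38 (mm10), without giving their roles or order. The gene annotation used by the authors is not given in the sources used here. The tdTomato and large T antigen transgenes have no row in the tables, so their expression was not analysed here.

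The authors deposited a table of expected counts per gene symbol, with column names that, per the file headers, are those of RSEM gene-level results. The values are estimated counts, which split reads shared between genes and need not be whole. Between 651 and 871 values per library were not whole numbers, and all were rounded to whole numbers before any count test. The authors also deposited a table of TPM values (transcripts per 1000000), which correct for transcript length and sum to 1000000 per library within rounding. The TPM values were used only for an alternative test. Both tables hold 23412 genes and 6 columns of samples, with no sample column left unmapped. The 13 mitochondrially encoded genes of a fixed list were not among the rows, so that list was not tested.

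Library totals ranged from 20340909 to 24174254 estimated counts. A floor of 3 counts corresponds to 0.124 to 0.147 CPM in a library. Counting intervals are at 95% and, like the floors, cover counting error only, since amplified reads without molecular identifiers are not independent molecules. No 2 libraries agreed within sampling noise: the chi-square per degree of freedom within groups was between 41.05 and 236.3.

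Differential expression was tested with edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr by group (13237 genes kept), robust dispersion estimation, glmQLFit with robust settings and a two-sided glmQLFTest of transformed against control, with Benjamini-Hochberg adjustment and a threshold of 0.05. TMM factors were 0.933, 0.872 and 0.83 for the control and 1.092, 1.122 and 1.209 for the transformed libraries. The common biological coefficient of variation was 0.515. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Levels are CPM on TMM-scaled library sizes. Where a group had no count in any library, the fold was computed against 3 counts over the group and given as a lower bound. Where it had 1 to 3 counts, the ratio of group totals was given with its counting interval.

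Before the data were examined, 30 gene lists were fixed for islet biology, the cell cycle, tumour biology, stress and other cell types, and 616 of their 631 entries matched the tables, 8 of them by an older symbol. Each of 28 lists with at least 3 tested genes was tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were alternatives. The genes to be named were fixed by rule: Ppy, Pyy, Ins1, Ins2, Gcg, Sst, Trp53, Rb1, Cdkn1a, Cdkn2a, Mki67, Krt19 and Sox9; the 10 largest rises and 10 largest falls among named gene models past the threshold with a mean of at least 10 CPM and no overlap between groups; and up to 4 genes with the smallest p from each list. Some genes that the rule named are not reported here, and the counts of named genes over the alternatives leave them out. Other genes named in the text were chosen after their values were seen, and the text says so.

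The scripts were tested on simulated data made from the control means, real library sizes and the fitted spread, with 200 of 13237 genes changed. Of 12418 genes tested, 0%, 2%, 40% and 68% of changed genes were recovered at 1.5-fold, 2-fold, 4-fold and 8-fold, and 4 of 59 calls (6.78%) were false. The camera step found the changed p53 list and also called 1 unchanged list. In this simulation changes of 2-fold or less were therefore rarely recovered. Few genes were changed in it, whereas 27.3% of the tested genes passed in the real data. Recovery after this adjustment depends on that share, so these rates do not carry over to the real data.

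Alternatives changed the scaling (DESeq2 size factors, upper quartile, library totals, TMM without the 20 genes with the most counts), the filter (none, or 10 CPM in 3 libraries), the tool (DESeq2 1.42.0, limma-voom, voom with quality weights, limma on log2(TPM + 1) or log2(TPM + 0.1)), the threshold (0.01, 0.1, or glmTreat against 1.5-fold), the depth, the replicate number as a block, the sex-linked genes, and each library left out in turn. After the data were seen, a covariate for the presence of Y-linked counts, list counts without the libraries that stood apart, camera with an estimated correlation under this covariate or with a library left out, and gene families defined by symbol were added. Gene positions and overlapping exons were taken from GENCODE M21 on GRCm38, in which 131 of 132 named genes were found once, and 31 had an exon overlapping another gene. Because strand was not marked, values are uncertain by the reads of such neighbours for Rb1, Cdkn1a, Ube2c, Kif4, Fgg, Lrrtm4, Ccnd1, Ccnd2, Ghrl, Neurog3, Resp18, Fen1, Lig1, H2afx, Dnajb9, Jund, Trpm5 and Tspan8, among others with a neighbour on the other strand, while the neighbour of Pam is on the same strand. Figures and tables were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.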

Results

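RNA sequencing was used to measure gene expression in cells of the Ppy lineage from the pancreatic islets of 7-day-old mice. Ppy encodes pancreatic polypeptide, the hormone of islet gamma cells, and Cre recombinase driven from this gene switches on the red fluorescent protein tdTomato in cells that have used it and in their descendants. The control group had this lineage reporter alone. The group called transformed by the submitters also carried a Cre-activated transgene for the large T antigen, a viral oncoprotein known to bind p53 and the RB family of proteins. Each group had 3 libraries. Per the series description, a total of 100 cells per group was profiled, pooled from 3 mice. The labels do not say whether each library came from its own mouse, so p-values measure the spread between these libraries, part of which may be technical. Y-linked counts were 8004, 6242 and 0 in the control and 0, 0 and 4164 in the transformed libraries. The libraries of a group therefore do not all hold cells of the same mice, and sex was not balanced between the groups. The stated purpose was to describe the expression profile of Ppy-lineage cells with and without the antigen.

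The control libraries held 23386531, 20353775 and 21458613 estimated counts, and the transformed libraries 20340909, 24174254 and 22667013. Levels are given as CPM, counts per 1000000 of the TMM-scaled library size. A count was recorded for 14200 ± 397 genes in control libraries (SD, n = 3) and for 15850 ± 495 in transformed libraries (SD, n = 3). Transcripts of the 8 islet hormone genes took 31.4% ± 2.75 of the counts in control libraries (SD, n = 3) and 7.95% ± 2.5 in transformed libraries (SD, n = 3). Within the control group, log2 CPM correlated across genes at 0.951 to 0.965. Transformed replicates 1 and 2 correlated at 0.957, whereas transformed replicate 3 correlated with them at 0.887 and 0.889. On the second principal component, which held 14.7% of the variance, replicate 3 stood apart at 104.3, against -54.46 and -42.46 for transformed replicates 1 and 2 and between -10.92 and 12.50 for the controls.

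Genes of mitosis were among the largest rises in transformed cells, and hormone, fibrinogen and D-type cyclin genes were among the largest falls. In all, 3610 of the 13237 genes tested (27.3%) differed between transformed and control cells, 2052 of them higher and 1558 lower in transformed cells (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). A change of at least 2-fold was fitted for 1568 of the higher and 1203 of the lower genes, and a change of at least 8-fold for 535 and 288. In 3601 of the 3610 genes, the 3 transformed libraries did not overlap the 3 control libraries. Such separation was seen in 48% of all tested genes, where chance gives 10%. The balance of higher and lower genes depended on the processing. With upper-quartile factors 1697 genes were higher and 2046 lower, with library totals alone 3356 and 916, and with limma on log2(TPM + 1) 6219 and 641. The last of these also changes the tool, the length correction and the genes tested (11312), so its shift cannot be put down to scaling alone. The median log2 fold change of the genes tested in both settings went from 0.055 to -0.106, 0.433 and 0.832, respectively. Without control replicate 1, 2 or 3 the number of genes past the threshold was 2164, 2155 or 2349.

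By fitted log2 fold change, the 10 largest rises among genes with at least 10 CPM and non-overlapping groups were Ccnb1, Ube2c, Bub1, Neil3, Melk, Kif4, Kif23, Ska1, Depdc1a and Pbk. Fitted values of genes with no control count depend on the model. Their rank against genes with a few control counts, such as Cdk1, Dtl and Cenpe below, is therefore not settled. Ccnb1 encodes cyclin B1, Ube2c a ubiquitin-conjugating enzyme of mitotic exit, Bub1 a spindle checkpoint kinase, Kif4 and Kif23 mitotic kinesins, Ska1 a kinetochore protein, and Neil3 a DNA glycosylase. All but Pbk had no count in any control library. Ccnb1 reached 413 ± 76.2 CPM in transformed cells (SD, n = 3), at least 7880-fold higher than a floor of 3 counts over the control group (edgeR adjusted p = 9.38e-06). On the same floor Ube2c was at least 6660-fold, Bub1 at least 3900-fold, Neil3 at least 3180-fold, Melk at least 3140-fold and Kif4 at least 2940-fold higher. Kif23, Ska1 and Depdc1a were at least 2510-fold, 2010-fold and 1780-fold higher. These bounds cover counting error only, since amplified reads are not independent molecules. Pbk, a mitotic kinase gene, had 2 counts over the control group and 49243 over the transformed group, a ratio of 18500 with a 95% counting interval of 5110 to 153000. Exons of Ube2c and Kif4 overlap those of Tnnc2 and Pdzd11 on the other strand, and the library kit does not mark strand, so reads of these pairs cannot be told apart.

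Nearly all fixed genes of DNA replication and every fixed gene of mitosis were higher in transformed cells in the edgeR test. Of 40 genes of the G1/S and DNA replication list, 39 were higher and none lower, with a median log2 fold change of 4.78. Of 47 genes of the G2/M and mitosis list, all 47 were higher, with a median of 8.25, which was the same with genes of 3 or fewer control counts set to their bound or counted ratio. Adjusted over the list alone, the counts were again 39 and 47. With the replicate number as a block, 38 and 39 passed as higher, and without control replicate 3, 39 and 46 did. Mki67, the gene of the Ki-67 proliferation antigen, rose from 1.05 ± 0.802 to 747 ± 161 CPM (SD, n = 3 each), a log2 fold change of 9.43 ± 0.56 (SE, edgeR adjusted p = 4.71e-05, and 10.3 without control replicate 1). Mcm3, a subunit of the replicative helicase, rose by 7.55 ± 0.26 on the log2 scale (SE, adjusted p = 3.46e-06). Fen1 and Lig1, which process and join lagging-strand fragments, rose by 4.34 ± 0.20 and 4.11 ± 0.20 (SE). Smc4, a condensin subunit, rose 24.8-fold. Cdk1, the kinase that drives entry into mitosis, had 4 counts over the control group and 38325 over the transformed group, and Cenpe, Tpx2 and Dtl had at most 3 over the control group. The fitted log2 fold change of Cdk1 was 12.7, and 12.1 and 14.0 without control replicate 1 or 3, that of Tpx2 was 12.2, and 11.6 and 13.2 without control replicate 1 or 2, and the single control count of Dtl was in replicate 3. The ratio of Cenpe was 7390 with a 95% counting interval of 2040 to 61000. The ratios of Tpx2 and Dtl were 5310 (1820 to 25700) and 8080 (1450 to 319000). Both lists were past the threshold in the camera set test (adjusted p = 3.19e-63 for G1/S and 1.25e-107 for G2/M), and each had an adjusted p of 0.00748 with an estimated correlation. The single G1/S gene not past the threshold was Ung, named here after its value was seen.

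Genes of DNA repair rose together with those of replication. Of 31 genes of the repair and damage checkpoint list, 27 were higher and none lower over all genes, and 29 were higher adjusted over the list alone. The median log2 fold change was 4.06 (camera adjusted p = 1.32e-25, and adjusted p = 0.00748 with an estimated correlation). H2afx, the histone variant phosphorylated at DNA breaks, rose by 3.23 ± 0.21 on the log2 scale (SE, n = 3 each, adjusted p = 3.37e-05). Brca1 and Exo1 each had 2 counts over the control group, with ratios of 2240 (95% counting interval 619 to 18500) and 1800 (497 to 14800). Rad51ap1 rose from 0.075 ± 0.130 to 124 ± 33.6 CPM (SD, n = 3 each). All 4 of its control counts were in replicate 3. Its log2 fold change of 10.67 was 10.1 without control replicate 1. Without control replicate 3 it was 14.5, a fitted value that depends on the model because no control count is left.

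**Figure D1:**
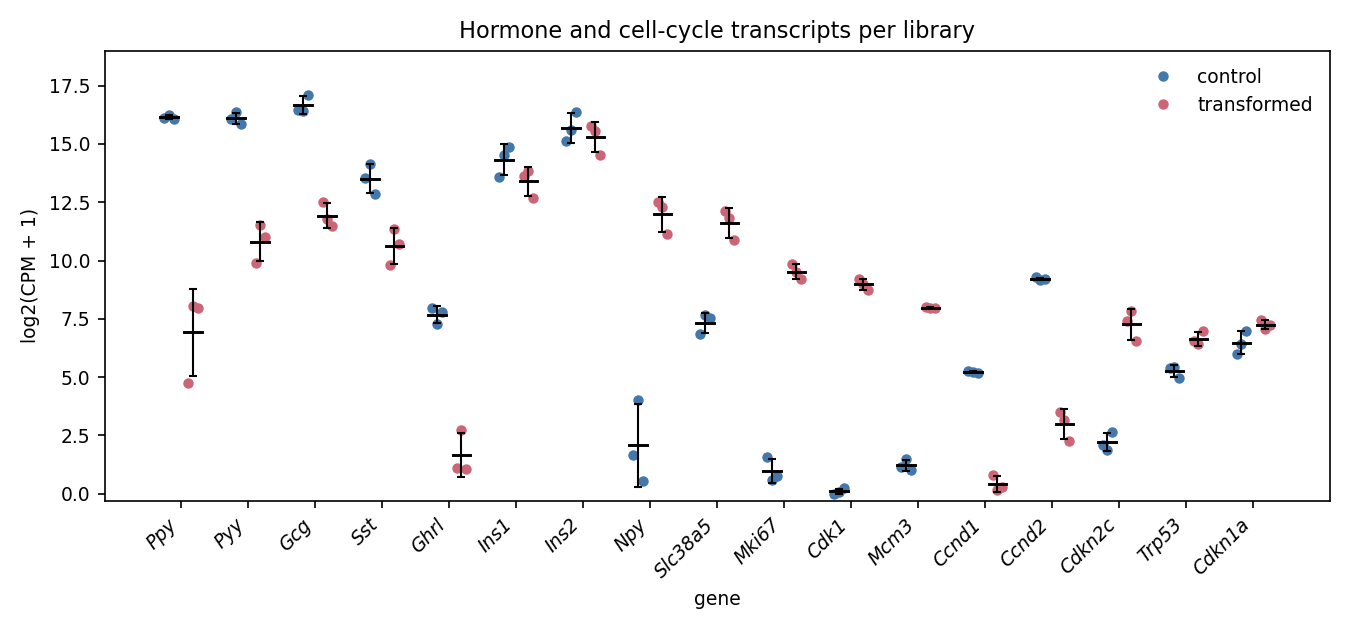
Levels of 17 hormone, cell-cycle and p53-pathway genes in each library as log2(CPM + 1), with points for the 3 control and 3 transformed libraries, a line at the mean and bars of 1 SD. Ppy went from 72810 to 179 CPM, Pyy from 70940 to 1990 CPM and Mki67 from 1.05 to 747 CPM, and the groups overlap at Ins1 and Ins2.

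The RB pathway list held changes in both directions. Of 18 genes tested, 9 were higher and 2 lower (11 and 3 adjusted over the list alone), and the list did not pass the set test (camera adjusted p = 0.0561), nor with an estimated correlation (adjusted p = 0.24). At the preset correlation it passed with Y-linked counts as a covariate (adjusted p = 0.0263) and without control replicate 1 or 2 or transformed replicate 2 or 3 (adjusted p 0.0279 to 0.0418), in each of which the adjusted p with an estimated correlation was 0.258 or higher. Fry, which tests a set against no change, gave an adjusted p of 0.00296. The 2 that fell were cyclins D1 and D2, whose products activate the kinases that phosphorylate RB. Ccnd1 went from 36.2 ± 1.11 to 0.366 ± 0.351 CPM (log2 fold change -6.65 ± 0.67, SE, adjusted p = 0.000323, and -7.72 without transformed replicate 1), and Ccnd2 from 591 ± 25.1 to 7.44 ± 3.37 CPM (log2 fold change -6.32 ± 0.39, SE, adjusted p = 3.37e-05), SD and n = 3 for each level. Among the genes that rose, Cdkn2c, an inhibitor of cyclin D kinases, was 43.4-fold higher (adjusted p = 0.000119) and Rbl1, the RB relative p107, 18.6-fold higher (adjusted p = 4.31e-05). Cdkn2a, which encodes p16 and p19ARF, had no count in control libraries and 2.54 ± 0.296 CPM in transformed libraries (SD, n = 3), at least 48.8-fold higher on a floor of 3 counts over the control group (adjusted p = 0.00994). Trp53 rose 2.68-fold (log2 fold change 1.43 ± 0.23, SE, adjusted p = 0.00287). Rb1 was 2.71-fold higher (adjusted p = 0.0376), but its CPM of 31.3 in transformed replicate 3 lay within the control range of 20.3 to 31.5. Its call was lost without any library other than transformed replicate 3 (adjusted p 0.0783 to 0.12). It was also lost with upper-quartile factors, limma-voom, the replicate block and Y-linked counts as a covariate (adjusted p = 0.0527, 0.0866, 0.0927 and 0.0905). Exons of Rb1 overlap those of Lpar6 and Rcbtb2 on the other strand.

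Target genes of p53 did not pass the test as a group. Of 30 tested, 1 was higher and 5 lower (1 and 4 adjusted over the list alone), with a median log2 fold change of -0.50 and a camera adjusted p of 0.229. The median was -0.109 with library totals alone and 0.269, opposite in sign, with limma on log2(TPM + 1). The median of all genes also moved, from 0.055 to 0.433 and 0.832, and that of the list lay below it in each setting. Without control replicate 3 the counts of higher and lower targets were 2 and 2. The gene that rose was Ckap2, which encodes a spindle protein and is also on the mitosis list (log2 fold change 6.19 ± 1.19, SE, adjusted p = 0.0148). Its call was lost without control replicate 3 (log2 fold change 6.15, adjusted p = 0.068), with no filter on low counts (adjusted p = 0.0519) and with the replicate block (adjusted p = 0.0645). Its log2 fold change was 5.60 and 7.40 without control replicate 1 or 2. Btg2, an antiproliferative gene, fell by 1.79 ± 0.25 on the log2 scale (SE, adjusted p = 0.00158). Trp53inp1 and Ercc5 fell by 1.29 ± 0.28 and 1.18 ± 0.30 (SE), but the call of Trp53inp1 was lost without control replicate 1 or 2 (adjusted p = 0.0569 and 0.0512) and that of Ercc5 without control replicate 1 or 3 or transformed replicate 1 (adjusted p = 0.0932, 0.0657 and 0.0605). Both calls were also lost with library totals alone (adjusted p = 0.0529 and 0.0712) and with limma on log2(TPM + 1) (adjusted p = 0.39 and 0.537). Cdkn1a, the p21 gene, had 90.9 ± 31.7 CPM in control and 152 ± 20.4 CPM in transformed cells (SD, n = 3 each), which did not pass the threshold (adjusted p = 0.0625). It passed as higher without control replicate 3 (log2 fold change 1.07, adjusted p = 0.0216), and also with library totals alone, with no filter, with DESeq2, with limma-voom, with voom and quality weights and with limma on log2(TPM + 1) (adjusted p = 0.00692, 0.0455, 0.0306, 0.0348, 0.0179 and 9.55e-05). Of 21 apoptosis genes, 4 were higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.653), and 3 were lower without transformed replicate 3. Cycs, the cytochrome c gene, rose 2.35-fold (adjusted p = 0.00211).

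Hormone genes of gamma, alpha, delta and epsilon cells were lower. Of the beta cell hormone genes, Iapp passed the threshold as lower in the edgeR test and the insulin genes did not, although the fold changes of Iapp and Ins1 were close. Ppy fell from 72810 ± 4480 to 179 ± 133 CPM (SD, n = 3 each), a log2 fold change of -8.67 ± 1.02 (SE, edgeR adjusted p = 0.00142). Its neighbour Pyy, the peptide YY gene, fell from 70940 ± 12100 to 1990 ± 1010 CPM (log2 fold change -5.16 ± 0.47, SE, adjusted p = 0.000212). In the GENCODE annotation of GRCm38, Ppy lies on the minus strand of chromosome 11 at 102099930 to 102101319, and Pyy on the same strand at 102106676 to 102107832. Gcg, the glucagon gene, fell 25.9-fold (log2 fold change -4.69 ± 0.41, SE, adjusted p = 0.000164). Ghrl, the ghrelin gene, fell 77.9-fold (log2 fold change -6.28 ± 0.78, SE, adjusted p = 0.0024), and 152 of its transformed counts were in replicate 2, without which the log2 fold change was -7.50. Sst, the somatostatin gene, fell 7.17-fold (log2 fold change -2.84 ± 0.47, SE, adjusted p = 0.00401), a call lost without transformed replicate 3 (log2 fold change -2.81, adjusted p = 0.054). Ins1 had a log2 fold change of -0.95 ± 0.40 (SE, adjusted p = 0.114) and Ins2 of -0.41 ± 0.42 (SE, adjusted p = 0.504). Ins1 passed as lower with DESeq2 (log2 fold change -0.944, adjusted p = 0.0346) and with the presence of Y-linked counts as a covariate (log2 fold change -1.284, adjusted p = 0.0198). Iapp, the amylin gene, named after its value was seen, had a log2 fold change of -1.09 ± 0.31 (SE, adjusted p = 0.0345). Its call was lost without control replicate 1, 2 or 3 or transformed replicate 1 (adjusted p = 0.0892, 0.0942, 0.1 and 0.0519), with library totals alone (adjusted p = 0.0819) and with limma on log2(TPM + 1) (adjusted p = 0.45). The insulin genes are close paralogs that can share reads. Of the 8 hormone genes, 6 were lower and none higher, and 7 were lower adjusted over the list alone. The list was past the threshold in the camera test (adjusted p = 4.22e-08), with an adjusted p of 0.0768 with an estimated correlation.

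Marker lists of gamma, alpha and delta cells were lower at the preset correlation and did not pass with an estimated one, and the list of beta cells did not pass with either. Of 9 gamma cell markers, 4 were lower and none higher (5 and 1 adjusted over the list alone), of 13 alpha markers 5 were lower and 1 higher (7 and 1), and of 8 delta markers 6 were lower and none higher over all genes and over the list alone. The camera adjusted p was 0.00139 for gamma, 0.00139 for alpha and 0.000212 for delta, and the adjusted p with an estimated correlation was 0.213, 0.396 and 0.213, respectively. Tm4sf4, an alpha cell marker, fell 5.43-fold (adjusted p = 0.000109), Rbp4, a retinol-binding protein gene on the delta list, fell 6.17-fold (adjusted p = 0.000226), and Hhex, a transcription factor of delta cells, fell 5.28-fold (adjusted p = 0.00264). The alpha marker that rose was Slc38a5, an amino acid transporter gene, from 165 ± 45.6 to 3293 ± 1300 CPM (SD, n = 3 each, log2 fold change 4.32 ± 0.38, SE, adjusted p = 0.000212). Of 14 beta cell markers, 4 were higher and 1 lower (5 and 1 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.246, adjusted p = 0.859 with an estimated correlation). Npy, the neuropeptide Y gene on the beta list, rose from 5.91 ± 8.02 to 4376 ± 1910 CPM (SD, n = 3 each, log2 fold change 9.54 ± 1.57, SE, adjusted p = 0.0103, and 11.7 without control replicate 2). Pdx1, Sytl4 and Trpm5 were 2.68-fold, 6.63-fold and 4.52-fold higher (adjusted p = 0.0151, 0.0209 and 0.0345), and each of these calls was lost without control replicate 2 (adjusted p = 0.0623, 0.0758 and 0.107). The call of Pdx1 was also lost without control replicate 3 or transformed replicate 1 (adjusted p = 0.0552 and 0.0543), that of Sytl4 without transformed replicate 2 (adjusted p = 0.0658), and that of Trpm5 without control replicate 1 or transformed replicate 1 or 2 (adjusted p = 0.0664, 0.113 and 0.0827). With the replicate block 2 beta markers were higher, and with Y-linked counts as a covariate 2 were lower. The same beta list had a camera adjusted p of 0.0367 without transformed replicate 3 (0.539 with an estimated correlation), and without control replicate 3 the gamma, alpha, delta and beta counts of lower genes were 2, 3, 3 and 0.

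Genes of the secretory granule were lower in transformed cells. Of 24 granule and hormone-processing genes, 15 were lower and 1 higher over all genes and adjusted over the list alone, with a median log2 fold change of -1.19 (camera adjusted p = 4.68e-09, adjusted p = 0.396 with an estimated correlation). The median was -0.82 with library totals alone and -0.286 with limma on log2(TPM + 1). In these settings the median of all genes was 0.433 and 0.832, against 0.055 in the main fit. Resp18, an endocrine granule protein gene, fell 15.1-fold (log2 fold change -3.92 ± 0.23, SE, adjusted p = 2.19e-05). Scg5, which encodes the chaperone of prohormone convertase 2, fell 10.9-fold (adjusted p = 0.00017). Pam, the peptide-amidating enzyme gene, fell 5.97-fold (adjusted p = 4.86e-05), and Cadps, a vesicle priming gene, fell 5.47-fold (adjusted p = 0.000202). The gene that rose was Pcsk1, prohormone convertase 1, named after its value was seen (log2 fold change 1.53 ± 0.31, SE, adjusted p = 0.00887). Of 22 endocrine transcription factors, 2 were higher and 5 lower, also adjusted over the list alone (camera adjusted p = 0.179, and with Y-linked counts as a covariate 0.0363 at the preset correlation and 0.643 with an estimated one). Neurog3, which starts endocrine differentiation, had 6.95 ± 2.57 CPM in control libraries (SD, n = 3) and no count in transformed libraries, at least 174-fold lower on a floor of 3 counts over the group (adjusted p = 0.00201). St18 fell 3.65-fold (adjusted p = 0.00079). Without transformed replicate 3, 7 of these factors were higher, and without control replicate 3, 1 was higher. Of 17 glucose sensing and excitability genes, 3 were higher and 6 lower (5 and 8 adjusted over the list alone, camera adjusted p = 0.249). Scn3a, a sodium channel gene, fell 21.1-fold (adjusted p = 7.33e-05), and Gipr, the incretin receptor gene, fell 9.24-fold (log2 fold change -3.21, adjusted p = 0.0208, and -4.34 without transformed replicate 1), the latter call being lost without any control replicate or transformed replicate 2 (adjusted p 0.0553 to 0.0754). Without control replicate 3, 1 gene of this list was lower, and with the replicate number as a block none was higher and 6 were lower.

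**Figure D2:**
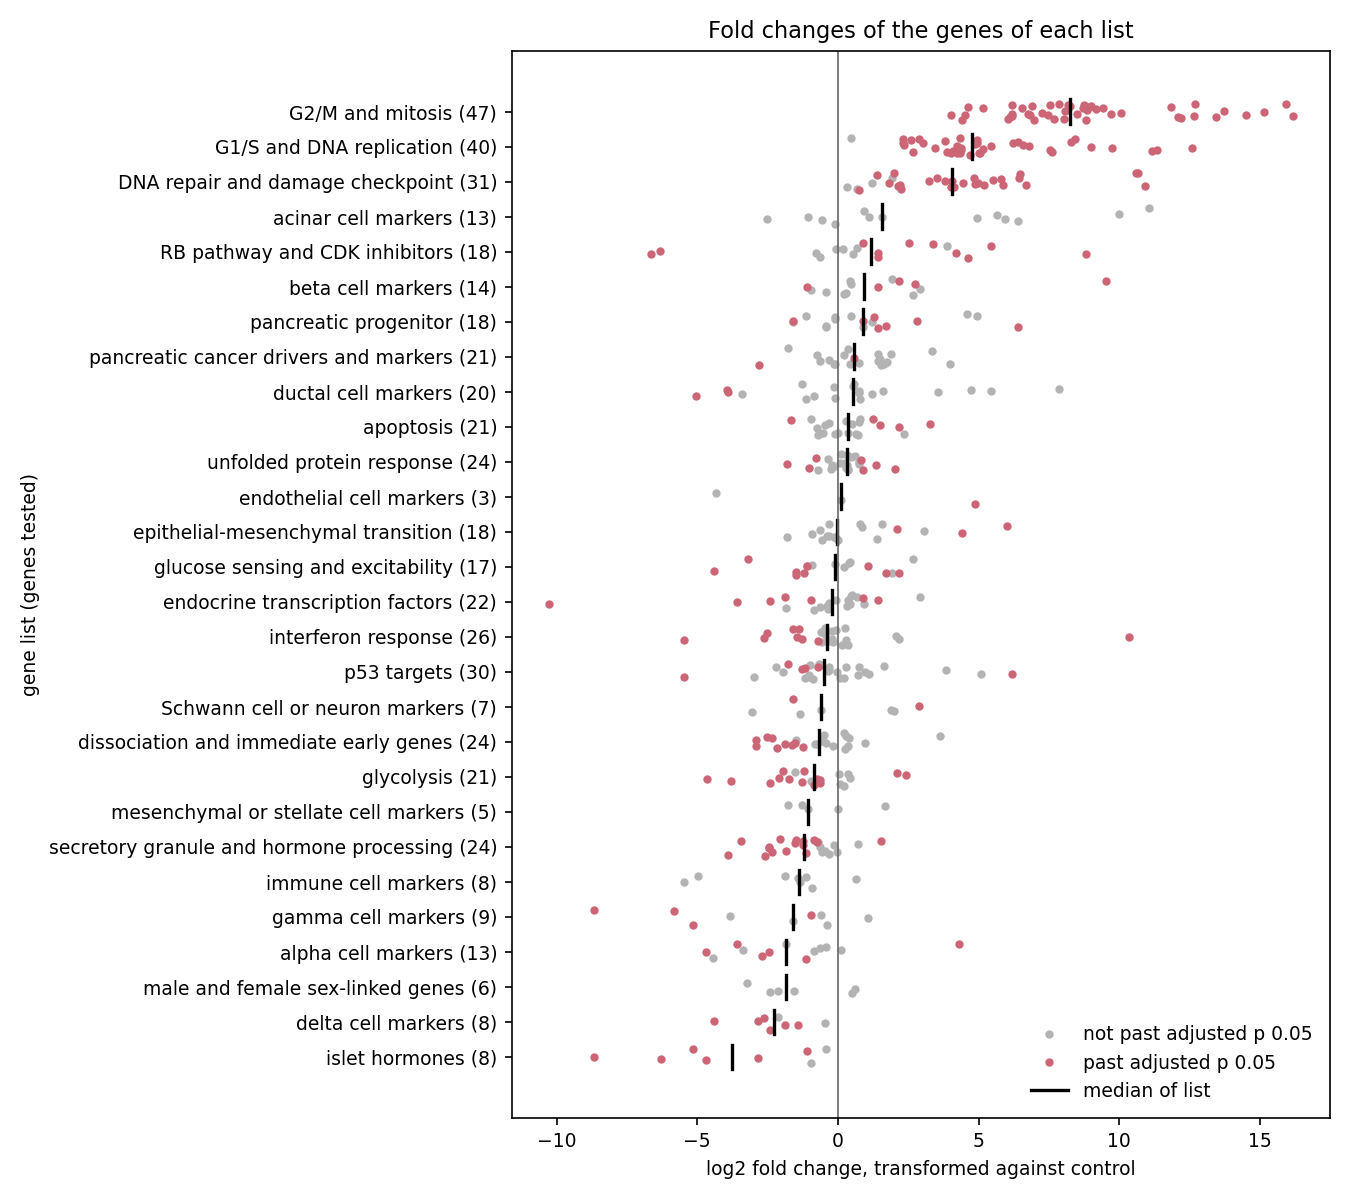
Fitted log2 fold change of transformed against control cells for the tested genes of 28 lists, with the number tested in brackets, points coloured by adjusted p under 0.05 and a bar at the median. All 47 mitosis genes and 39 of 40 replication genes were higher, 6 of 8 hormone genes were lower, and fitted values of genes with no count in a group depend on the model and are no bounds.

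Among the largest falls, genes of secreted and surface proteins stood beside Ppy, Ccnd1 and Ccnd2. Fgg and Fgb, which encode the gamma and beta chains of fibrinogen, lie on chromosome 3 at 83007724 to 83015049 and 83040141 to 83049863 in GRCm38. Fgg had 98.3 ± 26.4 CPM in control libraries (SD, n = 3) and no count in transformed libraries, at least 2550-fold lower on a floor of 3 counts over the group (adjusted p = 3.37e-05). Fgb fell 579-fold (log2 fold change -9.18 ± 1.36, SE, adjusted p = 0.00677, and -8.56 without transformed replicate 3), but all 35 of its transformed counts were in replicate 2, so this value is set by 1 library. Serpina10, a coagulation inhibitor gene, fell 435-fold (adjusted p = 0.00169), Lrrtm4, a synaptic adhesion gene, fell 313-fold (adjusted p = 0.000375), and Defb1, a defensin gene, fell 89.9-fold (adjusted p = 0.00226). These folds rest on few transformed counts: the log2 fold change of Serpina10 was -8.76, and -8.16 and -11.1 without transformed replicate 2 or 3; that of Lrrtm4 was -8.29, and -9.75 and -7.68 without transformed replicate 1 or 2; and that of Defb1 was -6.49, and -7.11 and -5.89 without transformed replicate 2 or 3. Ednrb, an endothelin receptor gene, had 3311 counts over the control group and 2 over the transformed group, a ratio of 0.000453 with a 95% counting interval of 5.49e-05 to 0.00164. Control replicate 3 held 106 of its control counts, both transformed counts were in replicate 3, and its adjusted p of 0.00404 became 0.0607 without transformed replicate 3 and 0.187 with limma-voom.

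Glycolysis and immediate early genes were lower on counts. Of 21 glycolysis genes, 12 were lower and 2 higher over all genes and adjusted over the list alone (median log2 fold change -0.85, camera adjusted p = 0.000249, adjusted p = 0.24 with an estimated correlation). The aldolase genes Aldoc and Aldoa fell 25.2-fold (adjusted p = 0.000241) and 5.31-fold (adjusted p = 0.000259), Eno2, an enolase gene, fell 13.9-fold (adjusted p = 0.000373), and Pfkl, a phosphofructokinase gene, fell 2.29-fold (adjusted p = 0.000887, and 0.338 with limma on log2(TPM + 1)). The 2 that rose, named after their values were seen, were Ldhb, a lactate dehydrogenase gene (log2 fold change 2.42 ± 0.47, SE, adjusted p = 0.00725, and 3.14 without control replicate 3), and Slc16a1, a lactate transporter gene (log2 fold change 2.09 ± 0.54, SE, adjusted p = 0.0232). The call of Slc16a1 was lost without any control replicate or transformed replicate 3 (adjusted p 0.0615 to 0.0858, log2 fold change 1.34 without the latter), with limma-voom (adjusted p = 0.0697) and with the replicate block (adjusted p = 0.0555). Of 24 dissociation and immediate early genes, 9 were lower and none higher (10 and 1 adjusted over the list alone, with 1 also higher with the replicate block or Y-linked counts as a covariate), with a median log2 fold change of -0.66 (camera adjusted p = 0.00306, adjusted p = 0.441 with an estimated correlation). Dnajb1, a heat shock co-chaperone gene, fell 3.70-fold (adjusted p = 0.000614), and Jund, a component of AP-1, fell 2.38-fold (adjusted p = 0.00328, and 0.267 with limma on log2(TPM + 1)). With limma on log2(TPM + 1) the medians of these lists were 0.092 for glycolysis and 0.042 for the immediate early genes, opposite in sign. In that setting the median of the genes also tested in the main fit was 0.832, against 0.055 in the main fit. Both list medians lay below the median of all genes in either setting.

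Interferon and unfolded protein response genes did not pass as groups. Of 26 interferon response genes, 1 was higher and 8 lower, also adjusted over the list alone (camera adjusted p = 0.11, adjusted p = 0.436 with an estimated correlation, and 0.0253 with fry), and 4 were lower without control replicate 3. Rsad2, an antiviral gene, had no control count and 7.37 ± 4.83 CPM in transformed libraries (SD, n = 3), at least 138-fold higher on a floor of 3 counts over the group (adjusted p = 0.00475), while Ifit3 fell 44.3-fold (adjusted p = 0.00786, and 0.059 with limma-voom and quality weights). Of 24 unfolded protein response genes, 4 were higher and 3 lower (5 and 3 adjusted over the list alone, camera adjusted p = 0.795), and 7 were higher without transformed replicate 3. Asns, the asparagine synthetase gene, rose 2.55-fold (adjusted p = 0.00146), and Dnajb9, an endoplasmic reticulum co-chaperone gene, fell 3.50-fold (adjusted p = 0.00572). Xbp1, a transcription factor of this response, fell 1.71-fold (adjusted p = 0.00484) on counts but had a log2 difference of 0.17 with limma on log2(TPM + 1) (adjusted p = 0.424). The median of all genes was 0.055 on counts and 0.832 in that setting, and Xbp1 lay below it in both.

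Pancreatic cancer markers showed no shared change over the group and were high in transformed replicate 3 alone. Of 21 tested genes of the cancer driver and marker list, 1 was higher and 1 lower, and none in either direction adjusted over the list alone (camera adjusted p = 0.668). The gene that was lower, Cd44, which encodes a hyaluronan receptor, fell 6.99-fold (log2 fold change -2.81, adjusted p = 0.0369, and -3.84 without transformed replicate 3), a call lost without control replicate 2 or 3 or transformed replicate 1 or 2 (adjusted p 0.074 to 0.124). The mean log2(CPM + 1) of the list was 2.98, 2.98 and 3.12 in control libraries and 2.00, 2.40 and 5.17 in transformed replicates 1, 2 and 3. Without transformed replicate 3, 9 genes of the list were lower and 1 higher, and the camera adjusted p was 0.0137 at the preset correlation and 0.334 with an estimated one. Without control replicate 3 none passed in either direction, with the replicate block 2 were higher, and with Y-linked counts as a covariate 2 were lower. Krt19, a keratin gene of duct cells and ductal tumours, had 17.2, 20.7 and 672 CPM in the transformed libraries and at most 2.14 CPM in the control libraries. Its log2 fold change of 7.86 ± 2.33 (SE) was not past the threshold (adjusted p = 0.0647), and without transformed replicate 1 or 3 it was 8.41 (adjusted p = 0.0413) or 4.22 (adjusted p = 0.0264). With limma on log2(TPM + 1) Krt19 also passed (adjusted p = 0.0465). Sox9, a transcription factor of ducts and pancreatic progenitors, had 40.6 ± 9.24 CPM in control libraries (SD, n = 3) and 0.676, 4.81 and 49.6 CPM in the transformed libraries (adjusted p = 0.574). Without transformed replicate 3 its log2 fold change was -3.87 (adjusted p = 0.00812), and with voom and quality weights it was -3.71 (adjusted p = 0.0091).

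Of 18 epithelial-mesenchymal transition genes, 3 were higher and none lower (1 and 0 adjusted over the list alone), with a camera adjusted p of 0.79. Without transformed replicate 3, 1 was higher and 7 were lower. Snai2, which encodes the transcription factor Slug, rose 21.2-fold (log2 fold change 4.41 ± 0.59, SE, adjusted p = 0.00127, and 5.25 without control replicate 2). Vim, the vimentin gene, had 8.75 ± 10.4 and 2.51 ± 0.287 CPM (SD, n = 3 each, adjusted p = 0.16). Of 18 pancreatic progenitor genes, 6 were higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.368), with 3 higher and none lower without control replicate 3 and 5 higher and 3 lower without transformed replicate 3. Dlk1, an imprinted gene of immature endocrine cells, rose 6.99-fold (log2 fold change 2.81 ± 0.31, SE, adjusted p = 0.000483).

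Markers of exocrine cells differed between the transformed libraries. The 30 acinar marker genes took 0.00147%, 0.38% and 0.779% of the counts in transformed replicates 1, 2 and 3 and between 0.00803% and 0.0126% in control libraries. Reg1, a secreted acinar protein gene, had 0, 1278 and 2489 CPM in the transformed libraries, and Amy2a5, an amylase gene, had 0, 1086 and 1566 CPM, against at most 1.80 and 2.70 CPM in control libraries. The count filter needs counts in as many libraries as a group holds. Markers with counts in transformed replicates 2 and 3 and almost none elsewhere, such as Ctrb1 and Cpa1, were therefore not tested. Without control replicate 3 the filter kept 26 acinar markers, with a median log2 fold change of 8.41, and none passed. No acinar marker of the 13 tested with all libraries passed the threshold in the edgeR test (adjusted p = 0.0829 for Reg1 and 0.0955 for Amy2a5, camera adjusted p = 0.887). Without transformed replicate 1 these were 0.00903 and 0.0145, and the list had a camera adjusted p of 2.25e-13 at the preset correlation and of 0.215 with an estimated one. With DESeq2 Reg1 and Amy2a5 passed as higher (adjusted p = 0.012 and 0.0257), whereas Cela1, an elastase gene, passed as lower with DESeq2 (log2 fold change -2.51, adjusted p = 0.00872), with limma-voom (adjusted p = 0.0244), with voom and quality weights (adjusted p = 0.0103) and without transformed replicate 1 (log2 fold change -1.96, adjusted p = 0.0233). Amylases and trypsinogens are families of near-identical copies, so their reads can be shared. Ductal markers took 0.0815%, 0.124% and 0.772% of the counts in transformed replicates 1, 2 and 3 and 0.329% to 0.352% in control libraries. Of 20 ductal markers tested, 3 were lower and none higher (1 and 0 adjusted over the list alone, camera adjusted p = 0.471), and 7 were lower and 1 higher without transformed replicate 3, with a camera adjusted p of 0.000984 at the preset correlation and of 0.334 with an estimated one. Without control replicate 3, 1 was lower, with Y-linked counts as a covariate 2 were higher and 2 lower, and with the replicate block 1 was higher and 2 were lower. Dcdc2a fell 32.8-fold (log2 fold change -5.03, adjusted p = 0.000908, and -5.90 without transformed replicate 3).

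**Figure D3:**
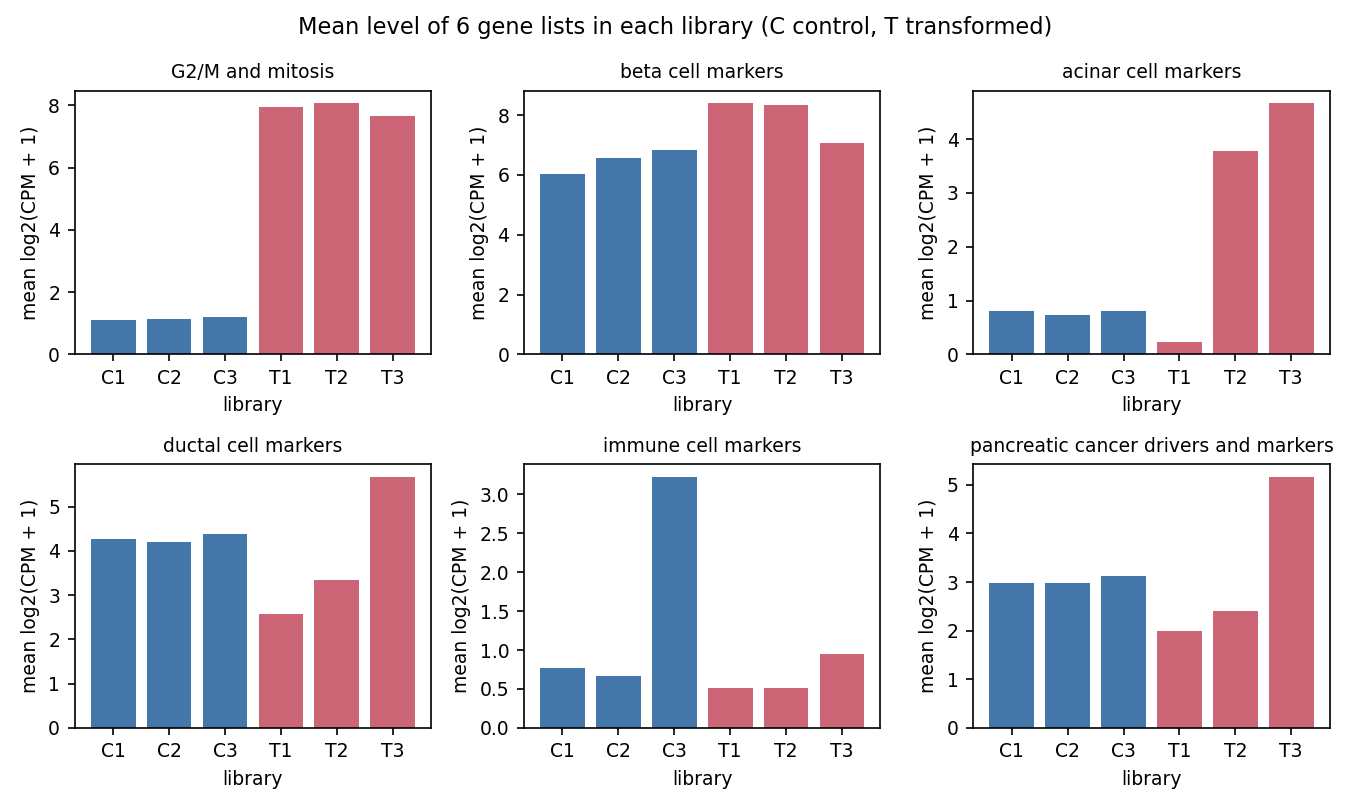
Mean log2(CPM + 1) over the genes of 6 lists in each library, with bars for control replicates 1 to 3 (C1 to C3) and transformed replicates 1 to 3 (T1 to T3) and axes that start at 0. The mitosis list separated the groups at 1.11 to 1.21 against 7.66 to 8.07, acinar markers reached 3.77 and 4.67 in T2 and T3 alone, ductal and pancreatic cancer markers were highest in T3 at 5.68 and 5.17, and immune markers stood at 3.23 in C3.

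Few markers of other cell types passed the threshold. Of 8 immune markers tested none passed the threshold (camera adjusted p = 0.471), with 1 higher without control replicate 3 and 1 lower without transformed replicate 3 and, with the replicate block, 2 lower, and their genes summed to 446 CPM in control replicate 3 and 28.2 to 53.6 CPM in the other libraries. Lyz2, a macrophage lysozyme gene, had 114 CPM in control replicate 3 and at most 1.99 CPM elsewhere. None of 5 mesenchymal markers tested passed (camera adjusted p = 0.656). Among 3 endothelial markers Plvap was higher (log2 fold change 4.88, and 6.06 without control replicate 1, adjusted p = 0.0219, and 0.0847 and 0.0608 without control replicate 2 or transformed replicate 1, list camera adjusted p = 0.953), and 1 of them was lower without transformed replicate 3. Among 7 Schwann cell or neuron markers Tubb3 rose 7.37-fold (log2 fold change 2.88, adjusted p = 0.0114, and 2.28 without transformed replicate 2) and Elavl4 fell 2.99-fold (adjusted p = 0.0145, and 0.0576 and 0.0569 without control replicate 1 or 2), with a list camera adjusted p of 0.668. No red blood cell marker passed the count filter, and their genes summed to 46.03 CPM in transformed replicate 2, where 3 of them had at least 10 counts, and to at most 0.2254 CPM in the other libraries. None of the 6 sex-linked genes passed (camera adjusted p = 0.79), and 2 were higher without control replicate 3. Ddx3y, a Y-linked gene, had 168 and 161 CPM in control replicates 1 and 2, 61.4 CPM in transformed replicate 3 and no count in the other libraries. Xist, the transcript of the inactive X chromosome, named after its values were seen, had 226 CPM in control replicate 3, 164, 70.1 and 89.4 CPM in transformed replicates 1, 2 and 3, and at most 0.688 CPM in control replicates 1 and 2, so transformed replicate 3 held both transcripts.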

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

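The counts of genes stayed within 1.5 times their main values (3610 genes, 2052 higher and 1558 lower) under most alternatives, with these exceptions. Library totals alone gave 3356 higher and 916 lower genes. Limma on log2(TPM + 1) gave 6860 genes (6219 higher, 641 lower), on log2(TPM + 0.1) 6725 (6120 and 605), and on log2(TPM + 1) with no filter 6150 (5581 and 569). The cause of these shifts was not tested. Stricter criteria passed fewer genes by construction: 2063 (1212 and 851) with glmTreat against 1.5-fold and 1680 (1013 and 667) at an adjusted p under 0.01. Leaving out a library gave 2155 to 4313 genes, 1361 to 2276 higher and 780 to 2037 lower, lowest in total without control replicate 2 and highest without transformed replicate 3. Of the 3610 genes, 3346 were past the threshold in the same direction without transformed replicate 3. The number of lists past the threshold was 10 and fell to 3 when camera estimated the correlation between genes. It was 12 with fry and 10 to 14 with a library left out. The replicate numbers were not taken as pairs, because nothing in the labels says that they mark a shared litter, day or batch. Deviations of same-numbered libraries correlated at 0.034, 0.001 and 0.069, and those of the other pairings at -0.07 to 0.041, which does not settle the question. With the number as a replicate block, 3031 genes (1689 higher, 1342 lower) and 10 lists passed. Of 97 named genes past the threshold, 65 stayed past it under all of 20 alternatives that tested them and 71 under all 6 left-out libraries, and 96 kept their direction throughout. The exception was Xbp1, whose log2 value was 0.17 with limma on log2(TPM + 1). In that setting the median of all genes moved from 0.055 to 0.832, and Xbp1 lay below the median in both settings. Its change of sign therefore came with a shift of the genes as a whole. Thinning the libraries to the shallowest gave 3613 genes.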

Other observations

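Families of genes defined by the start of their symbol were chosen and tested after the data were seen, by camera over 24 families. Of 18 centromere protein genes 16 were higher (adjusted p = 4.67e-15, and 0.023 with an estimated correlation). Of 30 kinesin genes 12 were higher and 4 lower (adjusted p = 1.07e-09, and 0.023 with an estimated correlation). Members of both families, such as Cenpe and Kif23, are also on the mitosis list, so these results are not independent of it. Of 20 nucleoporin genes 15 were higher with a median log2 fold change of 1.77 (adjusted p = 1.57e-09, and 0.023 with an estimated correlation). Nup62, a central pore protein gene named after its value was seen, rose by 2.81 ± 0.18 on the log2 scale (SE, n = 3 each). Of 49 histone genes 22 were higher and 1 lower (adjusted p = 1.51e-06, and 0.023 with an estimated correlation). Of 62 splicing factor genes 43 were higher and 3 lower (adjusted p = 1.4e-08, and 0.126 with an estimated correlation), among them Hnrnpab at 1.52 ± 0.16 and Srsf1 at 1.29 ± 0.16 (log2, SE), both also named after their values were seen. In the other direction, 11 of 24 complement and coagulation genes were lower and none higher (median log2 fold change -3.45, adjusted p = 9.31e-07, and 0.023 with an estimated correlation). These medians kept their sign with library totals alone, whereas that of the cytosolic ribosomal proteins went from -0.215 to 0.174. The median of all tested genes went from 0.055 to 0.433 with the same change, so the ribosomal median stayed below it. Igf2, an imprinted fetal growth factor gene singled out after its value was seen, had 35 counts over the control group and 9743 over the transformed group, a log2 fold change of 7.71 ± 0.39 (SE, adjusted p = 1.17e-05) with all 3 transformed libraries above the controls.

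In the following weighing, the test of transcript length and GC content was written before its result was seen. The tests of splits, of the freed hormone share, of sex, of hormone ratios and markers, and of the exocrine transcripts were written after results were seen. The 3610 genes were found in the real split, which was 1 of the 10 splits of the 6 libraries into 3 and 3 with as many, and the highest of the other splits gave 0. As many lists as the 10 of the real split passed in 7 of the 10 splits, the highest other split giving 16. With 10 splits no share under 0.05 can be reached. With an estimated correlation the real split gave 3 lists and the others at most 1. Each of the other splits put control and transformed libraries together on each side. Part of the group difference therefore stayed between the sides, and the rest added to the spread within them. The gene and list counts of these splits do not show what chance alone would give, so no conclusion is drawn from them.

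The rise of the replication, mitosis and repair lists was set against technical explanations. The smaller share of hormone transcripts would raise all other genes by 0.42 on the log2 scale, while the lowest median of the 3 lists under any scaling, or with limma on log2(TPM + 1), was 3.01, which argues against that share as the cause. Removing the trend with GC content and length left the median of the mitosis list at 8.09, from 8.25, with a length known for 93.8% of tested genes. With the presence of Y-linked counts as a covariate it was 8.56. Transcripts of the mitosis list were abundant in every transformed library and scarce in every control library. Their mean log2(CPM + 1) was 7.66 to 8.07 in the former and 1.11 to 1.21 in the latter. Cycling of cells with large T antigen, which the transgene would predict, would give such a pattern. The share of cells that cycled and the part of the antigen in it were not tested.

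Ppy, Pyy, Gcg, Sst and Ghrl fell further than Ins2. Their mean log2 ratio to Ins2 within a library was -1.67 ± 0.68 in control and -7.04 ± 1.11 in transformed libraries (SD, n = 3 each). The difference was -5.37 (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allows). No scaling of libraries can change such a ratio, so it restates the pattern free of scaling and tests no cause. These hormones were set against Ins2 after their values were seen, so the permutation p is not independent of that choice. A change in the mix of cells may account for part of it, with fewer gamma-, alpha- and delta-type cells and more of the beta type. The other 26 markers of these types had a median log2 fold change of -1.72 (quartiles -2.68 and -0.61) against -5.16 for the hormones, but 16 of them kept at least 10 CPM in transformed cells, so a change of mix and a change within cells cannot be told apart here.

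Acinar transcripts were raised in transformed replicates 2 and 3, and ductal ones, present in every library, were highest in transformed replicate 3. At least 26 of the 30 acinar markers reached 10 counts in each of replicates 2 and 3, against 3 in replicate 1 and 5 to 10 in the control libraries. The most abundant were Reg1 at 1278 and 2489 CPM, Ctrb1, named after its counts were seen, with 11768 and 32547 counts and Amy2a5 at 1086 and 1566 CPM, so a few acinar cells or their free RNA carried into the pools is a candidate source, with no sort or gate named that would remove it. Dilution of replicate 3 by cells that do not cycle would lower all its endocrine and cycling genes alike. The median log2 ratio to replicates 1 and 2 was -0.35 for the mitosis list and -1.22 for the beta markers, a difference of 0.86. Genes of a list move together and only 2 libraries give the spread of this difference, so dilution stays open. Replicate 3 also held Msln at 171 CPM, Ctse at 129 CPM, Muc1 at 210 CPM and S100a6 at 149 CPM, singled out after their values were seen, against at most 7.84 CPM in transformed replicates 1 and 2 and, in control libraries, at most 19.4, 1.51, 66.5 and 6.43 CPM, respectively. Replicate 3 was also the only library with at least 1 CPM of both Xist (89.4 CPM) and Ddx3y (61.4 CPM), so it may hold cells of more than 1 mouse. Which cells carried the ductal transcripts, whether they cycle and whether they belong to the Ppy lineage was not tested, and the pattern rests on 1 library.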
